A study of Mus musculus with 8 samples.

How the data were processed

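Intestinal RNA of wild-type C57BL/6 mice was measured in 8 libraries that the labels place in 4 groups of 2: saline control (NC), DSS-treated control (PC), exosomes without DSS (Ex) and exosomes followed by DSS (ExDSS). Per the labels' protocols, total RNA was isolated with Trizol and libraries were prepared with the QuantSeq 3' mRNA kit, in which reads start near the 3' end of polyadenylated transcripts. The deposited table holds whole-number counts per gene with 1 column per library, and the authors' alignment and counting used Bowtie2 and bedtools, per the submitters' processing notes, which also name edgeR and the mouse build mm9 and give no versions. All 8 columns matched 1 sample title each. The gene coordinates in the table were compared with a GRCm38 annotation: of 21982 genes matched by name and chromosome, 21909 (99.67%) overlapped the GRCm38 gene of that name, so coordinates are given as in the table and as GRCm38 positions. Whether counting used strand is not given in the sources used here, so overlapping genes on either strand can share reads.

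The table has 23282 lines with 23236 different gene names. Of these lines, 83 carry a name that occurs more than once, 27 carry a calendar date in place of a gene name (0.135% of all counts), 4764 have no count in any library, and none is mitochondrial. Lines were kept separate and none was merged. Overlapping features were counted more than once in places: 14 lines share the counts of another line exactly, among the 13452 lines with at least 100 counts in all.

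Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with TMM scaling, filterByExpr (a minimum count of 10 scaled to the library size in at least 2 libraries, and 15 in total), and the robust quasi-likelihood F test, in a model with 1 coefficient per group over all 8 libraries and 4 residual degrees of freedom. This left 14567 genes. Pooled DSS and exosome effects used an additive model of both factors. Adjusted p-values are Benjamini-Hochberg values over all genes tested and calls were made at an adjusted p under 0.05. Normalised CPM are the deposited counts scaled by the library total and its TMM factor. SE values of edgeR fold changes are the absolute log2 fold change divided by the square root of the F statistic. They are not standard errors fitted by the model. Fold changes against a group with no counts in both libraries are given as lower limits, computed against a floor of 3 counts per library. List medians at bound set such genes at this limit, or at no change where the level lies under the floor. Genes with no count in either group are left out of these medians, so they can exceed the fitted median and are not bounds. Shares of counts in single libraries carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since molecular identifiers are not mentioned in the sources used here.

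Before the data were examined, 37 gene lists were fixed, covering immune cells, epithelial lineages, gut regions, stroma, metabolism, stress and tissues that could contaminate a dissection. Of these, 36 were tested per contrast with camera (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists. Beside camera stand the same test with a correlation estimated from the data, and fry. The rule for naming genes was also fixed then: per contrast the 12 genes with the largest change in each direction among those called, with a mean of at least 5 CPM and, outside the interaction, groups that did not overlap, leaving out gene-model placeholders and antigen receptor segments; where fewer than 5 genes were called, the 10 with the smallest p at that mean; and the 3 members with the smallest p in each list described. Of the 42 genes called in the interaction, 1 placeholder was left out in this way. For the pooled DSS effect, 1 gene that the rule names is not reported here.

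The same scripts were tested on simulated counts drawn from the means and library sizes of these samples, with 200 genes changed by known folds. With an ordinary spread (dispersion 0.1), edgeR recovered 8.96% of 2-fold, 59.7% of 4-fold and all 16-fold changes between PC and NC over 14066 genes, and 1.49%, 20.9% and 90.9% of them in the interaction over 14028 genes. With the dispersion estimated from these libraries (1.173), edgeR recovered none of the changes of up to 16-fold in either test, while DESeq2 called 109 genes between PC and NC, 88 of them unchanged. At that dispersion, neutrophil genes raised 4-fold in PC had a camera adjusted p of 0.00505 with the preset correlation. It was 0.512 with an estimated correlation, and fry gave an adjusted p of 0.165. Each of the 3 tests called 0 unchanged lists. Simulated genes were drawn independently, so false calls from correlated genes were not tested.

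Alternatives covered RLE and upper-quartile factors, TMM without the 50 most abundant genes, total counts alone, 2 other filters, the quasi-likelihood fit without its robust option, the replicate number as a block, fits of only the groups compared, limma-voom, DESeq2 1.42.0 with its own filter over 18518 genes, looser and stricter thresholds and leaving out each library. Chosen after the data were seen were fits without libraries that stood apart, a term for libraries with missing transcripts, a fit without Rn45s, and the correlation of DSS responses without abundant genes missing from NC 2 or an ExDSS library. In the model with 1 coefficient per group, the term for missing transcripts was estimated from NC 1 and NC 2 alone, since both ExDSS libraries carry it. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.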

Results

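Mice of the C57BL/6 strain were given 1 mg of bovine colostrum exosomes, small membrane vesicles secreted into milk, by gavage each day for 3 weeks, or buffer in their place, and then 3% dextran sodium sulfate (DSS) in drinking water for 6 days or no DSS. DSS is a sulfated polysaccharide that injures the gut epithelium and is used to induce colitis. RNA of intestinal tissue was sequenced from 2 libraries in each of 4 groups, labelled NC (neither treatment), PC (DSS), Ex (exosomes) and ExDSS (exosomes, then DSS). The gut region is not given in the sources used here. Nothing in the labels says that the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

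Total counts were 11405200 and 12308537 in the libraries labelled NC 1 and NC 2, 10158929 and 10412457 in PC 1 and PC 2, 8813622 in Ex 1, 1163147 in Ex 2, and 9652586 and 10812469 in ExDSS 1 and ExDSS 2. The number of genes with at least 1 count ranged from 16123 to 16790 in NC 1, PC 1, PC 2 and Ex 1, and was 12683 in NC 2, 9825 in ExDSS 1, 11874 in ExDSS 2 and 8760 in Ex 2. Rn45s, the precursor of ribosomal RNA, held 53.5% of the counts of Ex 2 (95% interval 53.4 to 53.6%) and 13.1% of those of Ex 1. It held between 5.12% and 11.1% in NC 1, PC 1 and PC 2, and 0.407%, 0.874% and 0.665% in NC 2, ExDSS 1 and ExDSS 2. Digestive enzyme genes of pancreatic acinar cells held 8.31% of the counts of NC 2 (8.30 to 8.33%) and 19.2% of those of ExDSS 1 (19.1 to 19.2%), against at most 0.0101% in the other 6 libraries. The amylase gene Amy2a5 was the most abundant gene in both. Of 4895 genes with at least 20 CPM in NC 1, PC 1, PC 2 and Ex 1, the number under 1 CPM was 107 in NC 2 (2.19%), 534 in ExDSS 1 (10.9%), 97 in ExDSS 2 (1.98%) and 1382 in Ex 2 (28.2%). In the reverse direction, of 2980 genes with at least 20 CPM in NC 2, ExDSS 1 and ExDSS 2, the number under 1 CPM was 2 in NC 1 (0.0671%), 22 in PC 1 (0.738%), 19 in PC 2 (0.638%) and 10 in Ex 1 (0.336%). Across 16569 genes, which are not independent replicates, log2 CPM correlated at r = 0.983 between the PC libraries, 0.811 between the NC libraries, 0.71 between the ExDSS libraries and 0.508 between the Ex libraries. The highest value between groups was 0.981, for PC 2 and Ex 1. No 2 libraries agreed within sampling noise (chi-square per gene at least 22.0), so none was treated as a copy of another. This does not show whether they came from separate mice.

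**Figure D1:**
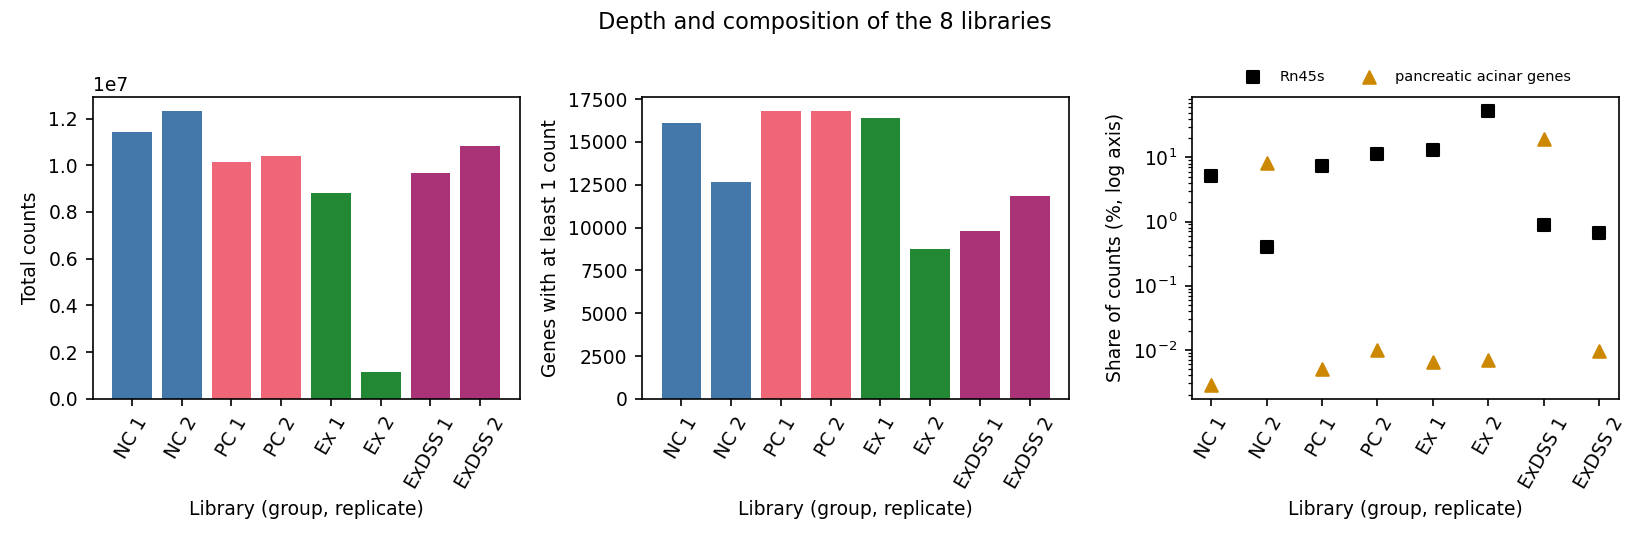
Total counts, genes with at least 1 count, and the percentage of counts in Rn45s (squares) and in pancreatic acinar genes (triangles, log axis) for each of the 8 libraries, with bars coloured by group. Ex 2 has the lowest total (1163147) and the highest Rn45s share (53.5%), and the pancreatic genes stand out in NC 2 (8.31%) and ExDSS 1 (19.2%).

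The first comparison asks what DSS did without pretreatment, with the groups taken as labelled. An exchange of the NC and PC labels, weighed below, stays open and would reverse the sign of this comparison. Several genes of neutrophils and of acute inflammation had a higher mean in the libraries labelled NC than in those labelled PC. S100a9 and S100a8, the subunits of the neutrophil protein calprotectin, were at 1136 ± 11.2 and 808 ± 23.2 CPM (SD, n = 2) in NC and at 0.569 ± 0.084 and 0.46 ± 0.238 CPM in PC. Il1b, a proinflammatory cytokine, was at 585 ± 210 against 2.4 ± 0.833 CPM, the chemokine Cxcl10 at 271 ± 66.2 against 0.896 ± 0.379 CPM, and the acute-phase gene Saa3 at 2979 ± 606 against 5.9 ± 1.02 CPM. Mptx1, which encodes a mucosal pentraxin, had 3.23 ± 4.44 CPM in NC and 6181 ± 2734 CPM in PC. S100a9 lies on chromosome 3 from 90692630 to 90695721, S100a8 beside it from 90669071 to 90670034, and Il1b on chromosome 2 from 129364580 to 129371120.

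None of these genes passed the test. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14567 genes between PC and NC, with 363 at an unadjusted p under 0.05 (100 higher and 263 lower in PC), while DESeq2 called 85 and limma-voom 2. The 10 genes with the smallest p were S100a9 (log2 fold change -10.93, SE 2.01, edgeR adjusted p = 0.19), S100a8 (-10.75, SE 2.01, 0.19), Serpina3f, Il1b, Cxcl10, Saa3, Hp, Wfdc21, Cxcl5 and Chil3, with edgeR adjusted p = 0.429 for the last 8 and log2 fold changes between -6.94 and -8.98. Serpina3f overlaps Serpina3g, so their reads may be shared. Without the library labelled Ex 1 edgeR called 3 genes, and 3 without Ex 2, all lower in PC. The median log2 fold change of all genes was 0.10 with TMM scaling and 0.29 with total counts.

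As groups, neutrophil genes were lower in PC (median log2 fold change -5.56, -5.34 with genes at 0 set at their bound; 19 of 20 members negative; camera adjusted p = 9.32e-36, and adjusted p = 0.0536 with an estimated correlation). None of the 20 members was called over all genes and 13 were lower adjusted over the list alone. Hdc, which makes histamine, had a log2 fold change of -7.66 (SE 1.91). Cytokine and chemokine genes had a median of -4.58 and -4.06 at bound (camera adjusted p = 3.1e-21; adjusted p = 0.289 with an estimated correlation), with 0 of 29 called over all genes and 9 lower adjusted over the list alone, among them Il11 (-6.86, SE 1.69). Interferon-stimulated genes had a median of -2.38 (camera adjusted p = 2.4e-15; adjusted p = 0.525 with an estimated correlation), with 0 of 38 called and 3 lower adjusted over the list alone. Their leading members were Cxcl10 and Cxcl9, which attract T cells, and the GTPase gene Gbp5 (-5.17, SE 1.52). Matrix proteases and inhibitors had a median of -1.94 (camera adjusted p = 1.08e-14; adjusted p = 0.289 with an estimated correlation), with 0 of 23 called and 8 lower adjusted over the list alone. Serpina3n was at 1310 ± 957 CPM in NC and 12.5 ± 1.31 CPM in PC, and the collagenase gene Mmp13 at 139 ± 107 and 2.82 ± 0.436 CPM. Monocyte and macrophage genes had a median of -2.29 (camera adjusted p = 2.23e-10; adjusted p = 0.598 with an estimated correlation), with 0 of 24 called and 1 lower adjusted over the list alone. C1qa, a complement gene, was at 785 ± 776 CPM in NC and 48.1 ± 14.5 CPM in PC. Without NC 1 the median of the cytokine and chemokine genes was -2.75.

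**Figure D2:**
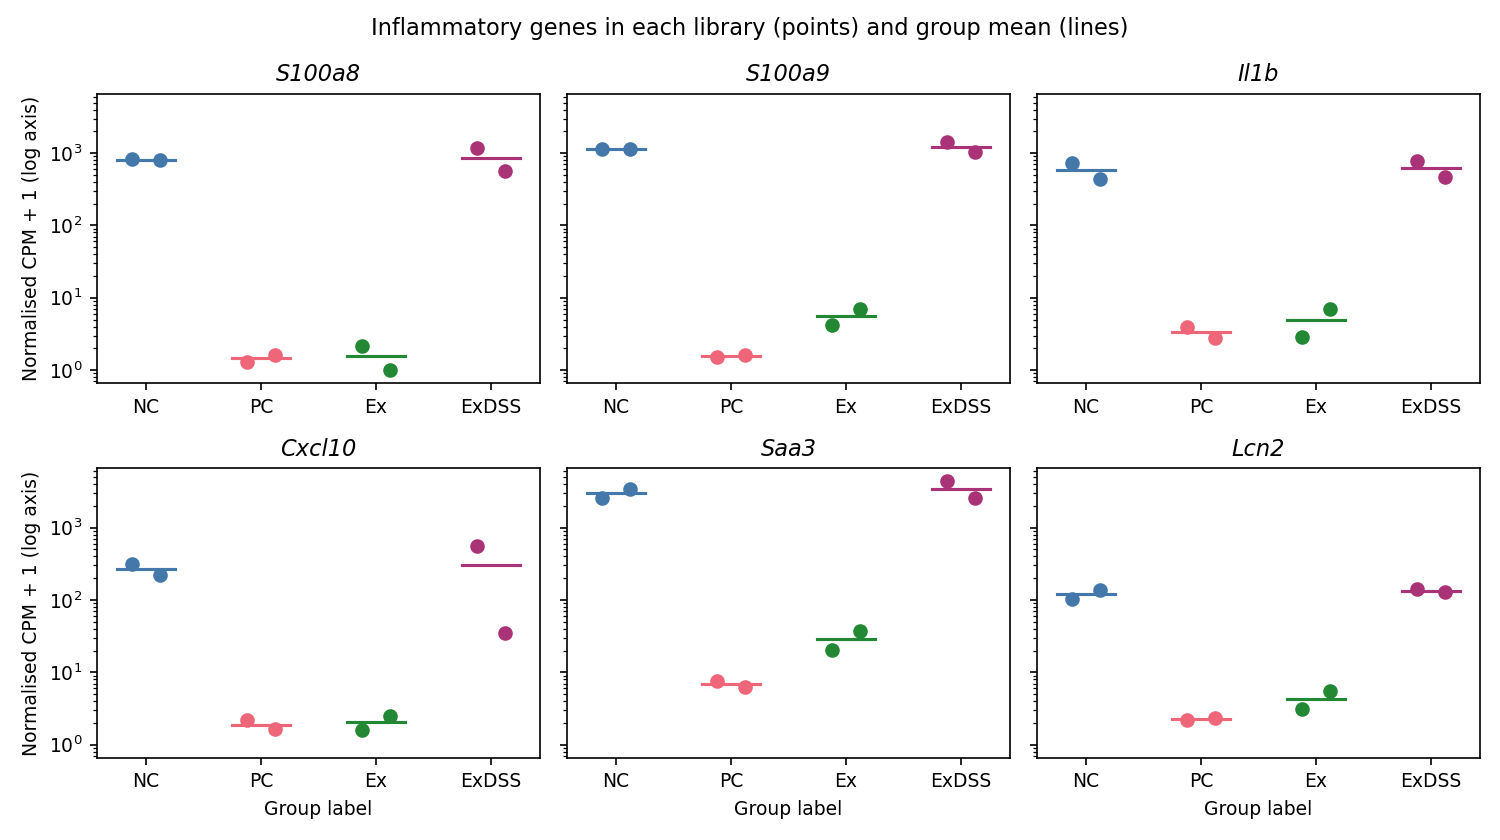
Normalised CPM plus 1 (log axis) of 6 inflammatory genes in each library (points) with the group mean (lines), by group label. All 4 libraries labelled NC or ExDSS lie above all 4 labelled PC or Ex for each gene, for example S100a9 at means of 1136 and 1230 CPM against 0.569 and 4.57 CPM.

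Genes of the epithelium and of proliferation gave values in both directions between the libraries labelled PC and NC. Antimicrobial defence genes had a median of -1.18 (camera adjusted p = 0.00796; adjusted p = 0.598 with an estimated correlation), with 0 of 22 called over all genes; adjusted over the list alone 2 were higher and 2 lower. Mptx1 had a log2 fold change of 10.89 (SE 3.21), against -6.57 (SE 1.53) for Lcn2, which binds bacterial siderophores. Cell cycle genes had a median of 0.90 (camera adjusted p = 0.00566; adjusted p = 0.741 with an estimated correlation), with 32 of 35 positive and none called or adjusted over the list alone. Cdk1, the mitotic kinase, was at 16.2 ± 19 CPM in NC and 127 ± 45.8 CPM in PC (SD, n = 2). Genes of distal colon patterning had a median of 5.30, and 1.80 at bound (camera adjusted p = 0.00768; adjusted p = 0.307 with an estimated correlation), with none of 9 called or adjusted over the list alone. Hoxb13 was at 2.95 ± 4.18 and 118 ± 49 CPM, Hoxd11 at 0.114 ± 0.0264 and 7.5 ± 7.72 CPM, and Hoxd12, with no count in NC, was at least 4.95-fold higher in PC, where it had 0.437 CPM in PC 1 and 1.96 CPM in PC 2 (at least 1.80-fold and 8.09-fold). Pancreatic acinar genes had a median of -10.53 (camera adjusted p = 2.21e-08; adjusted p = 0.741 with an estimated correlation), with 0 of 19 called over all genes and 19 lower adjusted over the list alone. Their counts in NC came from NC 2: Ctrb1, which encodes chymotrypsinogen, had 0.0664 CPM in NC 1 and 8028 CPM in NC 2. Camera no longer passed for pancreatic acinar genes without NC 2 (median 2.04, camera adjusted p = 0.346), for cell cycle genes without PC 1 (0.34, 0.230) and for distal colon genes without NC 1 (6.00, 0.255). Cell cycle genes had a median of 1.51 without NC 1 and 0.42 without NC 2, and antimicrobial genes -0.46 without NC 2. Tight and adherens junction genes (median 0.17, camera adjusted p = 0.878) and goblet cell and mucus genes (median -0.01, camera adjusted p = 0.372) did not pass, with 0 of 25 and 0 of 23 members called over all genes and 0 adjusted over the list alone in each. Cldn7 was at 350 ± 214 and 94.4 ± 3.58 CPM, and Spdef, a goblet cell transcription factor, at 92.6 ± 102 and 25.5 ± 12.4 CPM.

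The next comparison sets exosome pretreatment before DSS against DSS alone. Under an exchange of the NC and PC labels, which stays open, it would set exosomes and DSS against neither treatment. Several inflammatory genes had a higher mean in ExDSS than in PC: S100a9 was at 1230 ± 279 CPM and S100a8 at 865 ± 432 CPM (SD, n = 2), against 0.569 ± 0.084 and 0.46 ± 0.238 CPM in PC. Il1b was at 614 ± 212 against 2.4 ± 0.833 CPM, Saa3 at 3464 ± 1295 against 5.9 ± 1.02 CPM, and Hp, which binds free haemoglobin, at 321 ± 57.3 against 1.43 ± 1.09 CPM. Kif20b, a mitotic kinesin, was at 0.0419 ± 0.0593 CPM in ExDSS and 60.8 ± 20.8 CPM in PC. Creb3l1, a transcription factor of secretory cells, was at 3.22 ± 2.8 against 124 ± 22 CPM.

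edgeR's quasi-likelihood test called 0 of 14567 genes between ExDSS and PC, with 2763 at an unadjusted p under 0.05 (414 higher and 2349 lower in ExDSS), while DESeq2 called 1515 and limma-voom 1160. The smallest edgeR adjusted p was 0.177, for S100a9 (log2 fold change 11.05, SE 2.02) and S100a8 (10.84, SE 2.02). Kif20b (-9.96), Serpina3f (8.54), Wfdc21 (7.87), Hp (7.80), Il1b (7.99), Cxcl10 (8.36) and Saa3 (9.19) followed at an edgeR adjusted p of 0.228, as did Rprl3, a ribonuclease P RNA-like gene with no count in PC, which was at least 289-fold higher (104 CPM in ExDSS 1, at least 457-fold, and 27.6 CPM in ExDSS 2, at least 121-fold). Both ExDSS libraries lacked abundant transcripts, as given above, and the median log2 fold change of all genes was -0.51, or -0.91 with total counts. Without Ex 1 edgeR called 5 genes and without Ex 2 it called 6.

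Neutrophil genes had a median log2 fold change of 5.09, and 5.16 at bound (camera adjusted p = 1.29e-16; adjusted p = 0.223 with an estimated correlation), with 0 of 20 called over all genes and 10 higher adjusted over the list alone. Cytokine and chemokine genes had a median of 3.37, and 3.47 at bound (camera adjusted p = 8.96e-09; adjusted p = 0.599 with an estimated correlation), with 0 of 29 called and 6 higher adjusted over the list alone. Il11 (7.58, SE 1.75) and Ccl3 (6.97, SE 1.96), a chemokine for monocytes, were among its smallest p-values. For interferon-stimulated genes the median was 2.37 (camera adjusted p = 9.53e-11; adjusted p = 0.599 with an estimated correlation), with 0 of 38 called and 4 higher adjusted over the list alone. Matrix proteases and inhibitors (median 2.42, camera adjusted p = 4.63e-09; adjusted p = 0.533 with an estimated correlation) had 0 of 23 called and 5 higher adjusted over the list alone, with Serpina3n at 2372 ± 1044 CPM in ExDSS. Monocyte and macrophage genes (median 2.56, camera adjusted p = 5.6e-10; adjusted p = 0.599 with an estimated correlation) had 0 of 24 called and 4 higher adjusted over the list alone, with C1qa at 1442 ± 141 CPM and Fcgr1, an antibody receptor gene, at 109 ± 18.6 CPM. Without ExDSS 1 the median of the cytokine and chemokine genes was 1.76.

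Antimicrobial defence genes had a median of 1.30 in ExDSS against PC (camera adjusted p = 0.000158; adjusted p = 0.533 with an estimated correlation), with 0 of 22 called and 2 higher adjusted over the list alone. Reg1, a secreted lectin gene that the pancreas also expresses, was at 2925 ± 4137 CPM in ExDSS and 0.611 ± 0.247 CPM in PC (SD, n = 2), with 5851 CPM in ExDSS 1 and no count in ExDSS 2, where a count of 0 allows 0.252 CPM. Pancreatic acinar genes had a median of 12.26, and 11.90 at bound (camera adjusted p = 7.17e-09; adjusted p = 0.789 with an estimated correlation), with 0 of 19 called and 19 higher adjusted over the list alone. Ctrb1 had 29380 CPM in ExDSS 1 and 0 in ExDSS 2. Cell cycle genes had a median of -1.61 (camera adjusted p = 0.0175; adjusted p = 0.857 with an estimated correlation), with 32 of 35 negative and none called or adjusted over the list alone. Hmgb2, a chromatin protein of dividing cells, was at 11.9 ± 0.188 CPM in ExDSS and 117 ± 28.9 CPM in PC, and Bub1, with no count in ExDSS, was at least 21.8-fold lower there (9.90 CPM in PC 1, at least 29.8-fold, and 4.56 CPM in PC 2, at least 13.7-fold). The limits for Bub1 cover counting error only and do not allow for the transcripts missing from ExDSS. Camera no longer passed for pancreatic acinar genes without ExDSS 1 (median -4.38, camera adjusted p = 0.799) and for cell cycle genes without PC 1 (camera adjusted p = 0.200) or without ExDSS 2 (0.548). The antimicrobial median was 0.57 without ExDSS 1. Junction genes (median -0.21, mean -0.67, test upward at a camera adjusted p of 0.773) and goblet cell genes (median -0.02, mean -0.26, test upward at 0.362) did not pass. None of the members of either was called or passed adjusted over the list alone. Tjp1, a tight junction scaffold, was at 204 ± 273 CPM in ExDSS (396 CPM in ExDSS 1 and 10.8 CPM in ExDSS 2) and 10.3 ± 0.232 CPM in PC, and the mucin gene Muc1 at 42.8 ± 3.42 and 3.43 ± 0.404 CPM.

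Exosomes alone were compared with saline to ask what the vesicles did without DSS. Under an exchange of the NC and PC labels, which stays open, this would compare exosomes with DSS. Several neutrophil genes had a lower mean in Ex than in NC: S100a8 was at 0.562 ± 0.795 CPM against 808 ± 23.2 CPM in NC (SD, n = 2), S100a9 at 4.57 ± 1.97 against 1136 ± 11.2 CPM, and the neutrophil resistin-like gene Retnlg at 1.12 ± 1.59 against 263 ± 85.7 CPM. In Ex 2 a count of 0 allows a level of up to 4.47 CPM. Retnlb, a goblet cell product, was at 7.93 ± 3.54 CPM in Ex and 1057 ± 584 CPM in NC. Fxyd4, which encodes a regulator of the sodium pump, had no count in NC and was at least 360-fold higher in Ex, where its mean of 87.3 ± 124 CPM came from Ex 1.

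No gene passed for Ex against NC by edgeR's quasi-likelihood test (0 of 14567), with 774 at an unadjusted p under 0.05 (421 higher and 353 lower in Ex), while DESeq2 called 338 and limma-voom 0. The smallest edgeR adjusted p was 0.666, shared by S100a8 (-9.91, SE 1.99), Fxyd4, S100a9 (-8.03, SE 1.81), Retnlg (-7.41), Cxcl10 (-8.31), Gpr62 (8.83), Il1b (-7.38), Chil3 (-9.49) and Gm11517 (10.18), with Serpina3f (-7.13) at 0.677. Gpr62 was at 678 ± 938 CPM and Gm11517 at 546 ± 770 CPM in Ex, of which Ex 2 gave 1341 and 1091 CPM. Without the library labelled Ex 1, edgeR called 1619 genes, with Ex 2 alone standing for the group and assumed to vary like the others. The median of all genes was -0.27 with TMM, -0.49 with total counts and 0.11 with upper-quartile factors.

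Neutrophil genes had a median log2 fold change of -5.56 in Ex against NC, and -3.90 at bound (camera adjusted p = 7.54e-14; adjusted p = 0.256 with an estimated correlation), with 0 of 20 called and 10 lower adjusted over the list alone. Cytokine and chemokine genes (median -5.46, -2.88 at bound; camera adjusted p = 1.04e-09; adjusted p = 0.606 with an estimated correlation) had 0 of 29 called and 5 lower adjusted over the list alone, among them Ccl8 at 6.57 ± 7.19 against 507 ± 84.4 CPM. Interferon-stimulated genes (median -3.52, -3.50 at bound; camera adjusted p = 2.43e-11; adjusted p = 0.626 with an estimated correlation) had 0 of 38 called and 9 lower adjusted over the list alone. Monocyte and macrophage genes (median -3.04; camera adjusted p = 1.04e-09; adjusted p = 0.626 with an estimated correlation) had 0 of 24 called and 5 lower adjusted over the list alone, with Itgam, a myeloid integrin, at 1.84 ± 2.6 against 64.4 ± 30 CPM. Goblet cell and mucus genes had a median of -1.71 (camera adjusted p = 4.33e-06; adjusted p = 0.746 with an estimated correlation), with 0 of 23 called and 1 lower adjusted over the list alone. The median log2 CPM of this list was 5.38 in Ex 1 and 0.75 in Ex 2, against 5.71 and 7.52 in NC 1 and NC 2. The median fold change was -0.75 without Ex 2 (camera adjusted p = 0.00141) and -7.23 without Ex 1. Galnt12, a mucin glycosyltransferase gene, was at 10.5 ± 14.8 against 316 ± 307 CPM, with 21.0 CPM in Ex 1 and no count in Ex 2. Antimicrobial defence genes (median -2.19; camera adjusted p = 0.0028; adjusted p = 0.606 with an estimated correlation) had 0 of 22 called, and 2 higher and 5 lower adjusted over the list alone. Distal colon patterning genes had a median of 5.89, and 2.61 at bound (camera adjusted p = 0.000258; adjusted p = 0.256 with an estimated correlation), with 0 of 9 called and 6 higher adjusted over the list alone. Hoxd11 was at 18.6 ± 5.25 against 0.114 ± 0.0264 CPM, Hoxd13 at 34.5 ± 34 against 0.564 ± 0.798 CPM, and Hoxd12 was at least 6.11-fold higher in Ex, from 2.96 CPM in Ex 1 (at least 12.2-fold) and no count in Ex 2. Without Ex 1 the medians were -9.90 for neutrophil, -9.07 for cytokine and chemokine, -7.60 for interferon-stimulated, -9.87 for monocyte and macrophage, -6.68 for antimicrobial and 1.01 for distal colon genes. Without NC 1 they were -2.48 for cytokine and chemokine and -1.94 for interferon-stimulated genes. Without NC 2 the antimicrobial median was -1.46.

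The effect of DSS within pretreated mice was read from ExDSS against Ex. Several inflammatory genes had a higher mean in ExDSS than in Ex: S100a8 was at 865 ± 432 CPM against 0.562 ± 0.795 CPM in Ex (SD, n = 2), Cxcl10 at 299 ± 375 against 1.05 ± 0.62 CPM, and Cd74, the invariant chain of MHC class II, at 1531 ± 436 against 31.7 ± 36.3 CPM. A second set of genes had counts in Ex and none in ExDSS. Cyr61, a matricellular protein gene, was at least 5120-fold lower in ExDSS, Bbc3, a proapoptotic gene, at least 1441-fold lower and Aar2, a splicing factor gene, at least 504-fold lower. Their levels in Ex were 1698 ± 2395, 478 ± 669 and 167 ± 227 CPM and came mainly from Ex 2, where Cyr61 had 3392 CPM, against 4.91 CPM in Ex 1. From Ex 1 alone the limits were 14.8-fold for Cyr61, 15.1-fold for Bbc3 and 20.3-fold for Aar2. Both ExDSS libraries lacked abundant transcripts, as given above. These limits cover counting error only, so the true differences may be smaller.

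edgeR's quasi-likelihood test called 0 of 14567 genes between ExDSS and Ex, with 2881 at an unadjusted p under 0.05 (517 higher and 2364 lower in ExDSS), while DESeq2 called 2089 and limma-voom 505. The smallest edgeR adjusted p was 0.146, for Gm21949, Bbc3, Cyr61, Aar2, S100a8 (10.01) and Ncdn. Kif20b (-10.14), Clspn (-11.30), Prrc2b (-9.76) and Zbtb17 followed at 0.147. Gm21949, Ncdn and Zbtb17 had no count in ExDSS and were at least 484-fold, 432-fold and 247-fold lower. These limits came mainly from Ex 2, with 309, 279 and 149 CPM against 12.7, 8.08 and 15.1 CPM in Ex 1. From Ex 1 alone they were 38.2-fold, 24.4-fold and 45.6-fold. They too do not allow for the transcripts missing from ExDSS. Without Ex 1 edgeR called 1914 genes, without PC 1 it called 8 and without PC 2 also 8. The median of all genes was -0.29, and -0.72 with upper-quartile factors.

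Monocyte and macrophage genes had a median of 3.30 in ExDSS against Ex (camera adjusted p = 2.2e-10; adjusted p = 0.687 with an estimated correlation), with 0 of 24 called and 6 higher adjusted over the list alone; Fcer1g, an antibody receptor chain, was at 497 ± 87.3 against 13.4 ± 16.9 CPM. Interferon-stimulated genes (median 3.02, 2.73 at bound; camera adjusted p = 2.5e-10; adjusted p = 0.687 with an estimated correlation) had 0 of 38 called and 10 higher adjusted over the list alone, with Isg15 at 413 ± 96.2 against 11.6 ± 3.8 CPM. Neutrophil genes (median 5.03, 4.37 at bound; camera adjusted p = 1.38e-09; adjusted p = 0.627 with an estimated correlation) had 0 of 20 called and 10 higher adjusted over the list alone. Cytokine and chemokine genes (median 3.62, 1.55 at bound; camera adjusted p = 1.6e-05; adjusted p = 0.687 with an estimated correlation) had 0 of 29 called and 4 higher adjusted over the list alone. Antimicrobial defence genes (median 2.74; camera adjusted p = 1.79e-05; adjusted p = 0.687 with an estimated correlation) had 0 of 22 called and 6 higher adjusted over the list alone, with Retnlb at 739 ± 468 against 7.93 ± 3.54 CPM. Goblet cell and mucus genes (median 1.65; camera adjusted p = 5.88e-05; adjusted p = 0.721 with an estimated correlation) had 0 of 23 called and 1 higher adjusted over the list alone. Its median log2 CPM was 5.38 in Ex 1 and 0.75 in Ex 2, against 6.93 and 6.39 in ExDSS 1 and ExDSS 2. The median fold change was 0.74 without Ex 2 (camera adjusted p = 0.00923), 1.01 without ExDSS 2 and 7.92 without Ex 1. MHC class II genes (median 2.54; camera adjusted p = 8.81e-05; adjusted p = 0.687 with an estimated correlation) had 0 of 11 called and 1 higher adjusted over the list alone, with H2-DMa at 190 ± 110 against 10.7 ± 13 CPM. Their median was 1.61 without Ex 2. Without Ex 1 the medians were 9.71 for neutrophil, 7.83 for cytokine and chemokine, 7.31 for interferon-stimulated, 9.37 for monocyte and macrophage, 6.63 for antimicrobial and 8.28 for MHC class II genes.

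The interaction asks whether the response to DSS differed between mice with and without exosomes. Among the genes that passed it, S100a8 had a log2 interaction of 20.75 (SE 2.83, edgeR adjusted p = 0.00415) and S100a9 19.07 (SE 2.71, 0.00415). Il1b (15.38, SE 2.45, edgeR adjusted p = 0.0092), Cxcl10 (16.68, SE 2.66, 0.0092), Chil3 (18.10, SE 2.98, 0.0114), Saa3 (15.95, SE 2.73, 0.0151) and Lcn2 (12.02, SE 2.14, 0.0151) also passed. A log2 interaction adds the log2 difference of ExDSS from Ex to that of NC from PC, so it is not a single log2 fold change. The test equals a comparison of NC and ExDSS together with PC and Ex together, in which S100a9 was at 1136 ± 11.2 and 1230 ± 279 CPM (SD, n = 2), and Lcn2 at 120 ± 23.6 and 134 ± 10.8 CPM. If the labels of NC and PC were exchanged, which stays open, this comparison would set DSS against no DSS.

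edgeR called 42 of 14567 genes in the interaction at an adjusted p under 0.05, 38 with a positive and 4 with a negative value, and 2741 had an unadjusted p under 0.05. The 12 largest positive values among called genes with a mean of at least 5 CPM, gene-model placeholders left out, were those of Slc6a19 (21.50), an amino acid transporter of the small intestine, Stfa2l1 (21.26), a stefin of neutrophils, S100a8, the neutrophil collagenase gene Mmp8 (19.82), Wfdc12 (19.50), S100a9, Chil3, Irg1 (17.91), which makes itaconate in macrophages, Cxcl10, the serpin Serpina3h (16.56), Saa3 and the serpin Serpina3f (15.66). Slc6a19 and Stfa2l1 had no count in PC or Ex, Irg1 none in PC, and Mmp8 and Wfdc12 none in Ex, so their fitted values depend on how a 0 is treated and are not bounds. Slc6a19 was at 5.28 ± 7.38 CPM in NC and 84.0 ± 103 CPM in ExDSS (SD, n = 2), so single libraries gave most of its level. Negative values were those of Bbc3 (-15.89), Aar2 (-14.62) and Kif20b (-11.85), of which Bbc3 and Aar2 had no count in ExDSS. With total counts in place of TMM 6 genes were called, with RLE factors 67, with DESeq2 1659 and with limma-voom 327. A term for the 3 libraries that lacked abundant transcripts was estimated from NC 1 and NC 2 alone, since both ExDSS libraries carry it. Its result, given below, cannot show what missing transcripts did. edgeR called 0 genes without NC 1, without NC 2 or without ExDSS 1 (3061, 1772 and 2637 at an unadjusted p under 0.05), 6 were called without ExDSS 2, 7 without Ex 2, 15 without PC 1, 31 without PC 2 and 1700 without Ex 1. Without both libraries that held pancreatic transcripts, or with a term for the 3 libraries that lacked abundant transcripts, 0 were called, with 3382 and 333 at an unadjusted p under 0.05. A fit without NC 2, Ex 2 and ExDSS 1, chosen after the data were seen and with its spread taken from the PC pair alone, called 9416 genes in the interaction, and 3677, 10496, 3361 and 9541 for PC against NC, ExDSS against PC, Ex against NC and ExDSS against Ex.

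By group, neutrophil genes had a median log2 interaction of 10.78 (camera adjusted p = 4.62e-18; adjusted p = 0.192 with an estimated correlation), with 6 of 20 higher over all genes and 14 adjusted over the list alone. Cytokine and chemokine genes had a median of 9.26 (camera adjusted p = 1.66e-11; adjusted p = 0.525 with an estimated correlation), with 4 of 29 higher over all genes and 15 adjusted over the list alone, among them Il11 (13.78) and Cxcl5. The interferon-stimulated list (median 5.90, camera adjusted p = 4.44e-14; adjusted p = 0.525 with an estimated correlation) had 3 of 38 higher, namely Cxcl10, Gbp5 (11.23) and Cxcl9 (10.95), and 20 adjusted over the list alone. Matrix proteases and inhibitors (median 4.53, camera adjusted p = 8.81e-10; adjusted p = 0.525 with an estimated correlation) had 4 of 23 higher, including Serpina3n (14.10) and Serpina3g (12.46), and 9 adjusted over the list alone. Monocyte and macrophage genes (median 5.85, camera adjusted p = 1.77e-12; adjusted p = 0.525 with an estimated correlation) had 1 of 24 higher, Chil3, and 13 adjusted over the list alone. Fcgr1 (9.90, edgeR adjusted p = 0.0537) and C1qa (9.66, 0.0848) did not pass. Antimicrobial defence genes (median 3.83, camera adjusted p = 5.18e-05; adjusted p = 0.525 with an estimated correlation) had 2 of 22 higher, Saa3 and Lcn2, and adjusted over the list alone 7 higher and 3 lower. Reg3b, an antibacterial lectin gene, did not pass (12.88, SE 3.41, edgeR adjusted p = 0.111). Pancreatic acinar genes had a median of 21.05 (camera adjusted p = 1.39e-05; adjusted p = 0.693 with an estimated correlation), with 0 of 19 called over all genes and 19 higher adjusted over the list alone. Camera no longer passed for them without ExDSS 1 (median 4.21, camera adjusted p = 0.147) or without Ex 1 (20.54, 0.232). The median was 8.19 without NC 2. These list medians include fitted values of genes with no count in a group, depend on how a 0 is treated and are not bounds. With each such group set at its floor of 3 counts per library they were 9.15 for neutrophil genes (7 of 20 with a group at 0), 4.23 for cytokines and chemokines (10 of 29), 5.24 for interferon-stimulated (3 of 38) and 20.66 for pancreatic acinar genes (2 of 19). Without Ex 1 the medians were 10.45 for interferon-stimulated, 9.83 for matrix protease, 11.49 for monocyte and macrophage and 8.57 for antimicrobial genes. The levels of the pancreatic genes in NC and ExDSS came from NC 2 and ExDSS 1. Amy2a5 had an interaction of 22.92 (SE 5.93, edgeR adjusted p = 0.111).

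Over all 8 libraries, the pooled effect of DSS compared PC and ExDSS with NC and Ex. Under an exchange of the NC and PC labels, it would instead ask whether the response to DSS differed with exosomes. Ang4, an antimicrobial ribonuclease of the gut, was at 524 ± 176 CPM in PC and 317 ± 401 CPM in ExDSS, against 33.9 ± 10.8 CPM in NC and 10.7 ± 1.78 CPM in Ex (SD, n = 2). Its log2 fold change was 4.42 (SE 1.20, edgeR adjusted p = 1). Ang3 and Ang5, which share their coordinates and counts, were at 13.4 ± 2.75 CPM in PC and 11.9 ± 16.8 CPM in ExDSS, against 0.328 ± 0.194 CPM in NC and no count in Ex. Stc1 (-5.88, SE 2.20) had 3610 ± 5102 CPM in Ex, of which Ex 2 gave 7218 CPM and Ex 1 2.56 CPM, and 21.7 ± 5.94 CPM in NC, 3.56 ± 2.48 CPM in PC and 6.29 ± 1.78 CPM in ExDSS. Hoxc6 (-7.39) was likewise highest in Ex 2. edgeR called 0 genes for DSS, with 80 at an unadjusted p under 0.05, DESeq2 called 24 and limma-voom 0. Goblet cell and mucus genes had a median of 0.44 (camera adjusted p = 0.000635; adjusted p = 0.914 with an estimated correlation), with none of 23 called over all genes or adjusted over the list alone; Clca1 (1.62, SE 1.47) was at 13540 ± 13070 CPM in ExDSS and 3470 ± 1813 CPM in PC, against 3122 ± 1483 CPM in NC and 1584 ± 2147 CPM in Ex. Camera no longer passed for this list without Ex 2 (median -0.08, camera adjusted p = 0.258) or without ExDSS 2 (0.33, 0.0517). The median was 1.08 without Ex 1, 0.97 without NC 2, 0.98 without PC 1 and 0.85 without PC 2. Of 36 lists, 12 passed camera for DSS, 0 without Ex 2, 2 without ExDSS 2 and 7 without ExDSS 1.

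The pooled effect of exosomes compared Ex and ExDSS with NC and PC. H2-T3, a nonclassical MHC gene, was at 0.102 ± 0.145 CPM in Ex and 0.137 ± 0.194 CPM in ExDSS, against 24.1 ± 12.2 CPM in NC and 14.9 ± 15 CPM in PC (SD, n = 2). The mucin core glycosyltransferase gene B3gnt6 was at 0.0511 ± 0.0723 and 0 CPM against 8.25 ± 1.15 and 12.3 ± 10.4 CPM, and Shmt2, a mitochondrial enzyme of serine and glycine metabolism, at 183 ± 250 and 82.8 ± 96.3 CPM against 2.81 ± 3.16 and 7.4 ± 1.31 CPM. The pooled log2 fold changes were 7.68 for Frmd5, 5.56 for Gm10052, 5.16 for Skp2 and 5.71 for Parp8. Single libraries gave most of these levels. In Ex 2 and Ex 1, Gm10052 had 622 and 1.94 CPM, Skp2 121 and 3.58 CPM, Parp8 90.9 and 1.43 CPM, and Shmt2 359 and 6.13 CPM. In ExDSS 1 and ExDSS 2, Frmd5 had 120 and 0 CPM, Gm10052 96.4 and 5.45 CPM, Skp2 112 and 9.31 CPM, and Shmt2 151 and 14.7 CPM. edgeR called 0 genes for exosomes (adjusted p = 1 for each of these), with 255 at an unadjusted p under 0.05, DESeq2 called 35 and limma-voom 0. Tuft cell genes had a median of -0.92 (camera adjusted p = 0.0344; adjusted p = 0.991 with an estimated correlation), with none of 13 called over all genes or adjusted over the list alone. Avil, an actin regulator of tuft cells, had a log2 fold change of -4.40 (SE 2.04). The median log2 CPM of the tuft list was 1.61 in Ex 1 and 1.83 in ExDSS 2, between 1.89 and 3.37 in the NC and PC libraries, and -2.35, the value of a 0 count, in Ex 2 and ExDSS 1. Camera no longer passed without NC 2 (median -0.69, camera adjusted p = 0.239), Ex 1 (-1.53, 0.0865), Ex 2 (-0.35, 0.0778) or ExDSS 1 (-0.65, 0.0946). Pancreatic acinar genes had a median of 1.04 (camera adjusted p = 0.000202; adjusted p = 0.991 with an estimated correlation), with none of 19 called or adjusted over the list alone. This median was -6.86 without PC 1 (camera adjusted p = 0.0612), -4.84 without PC 2 and -8.31 without ExDSS 1 (0.0643), against 9.15 without NC 2, 10.08 without Ex 1 and 9.96 without Ex 2. Camera did not pass without NC 1 either (0.0854). Of 36 lists, 6 passed camera for exosomes, 12 without Ex 2, 2 without NC 2 and 3 without ExDSS 1.

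The DSS responses with and without pretreatment were correlated across genes. Log2 fold changes of PC against NC and of ExDSS against Ex, which share no library, correlated at r = -0.472 across 14567 genes, which are not independent replicates. Under an exchange of the NC and PC labels, which stays open, r would have the opposite sign. Leaving out each library gave values from -0.498 to -0.279, with -0.333 without NC 2, -0.367 without ExDSS 1 and -0.279 without Ex 1. Abundant transcripts were missing from NC 2 and both ExDSS libraries and a gene lost from both sides has a higher PC against NC and a lower ExDSS against Ex. Without 623 abundant genes missing from at least 1 of these libraries r was -0.470, without NC 2 and ExDSS 1 it was -0.334, and without NC 2, Ex 2 and ExDSS 1 it was -0.352. Partial losses are not removed by these fits, and the last 2 keep ExDSS 2. A return towards saline levels was not computed, since edgeR called 0 genes between PC and NC from which to measure it (363 at an unadjusted p under 0.05, 85 by DESeq2, 2 by limma-voom).

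**Figure D3:**
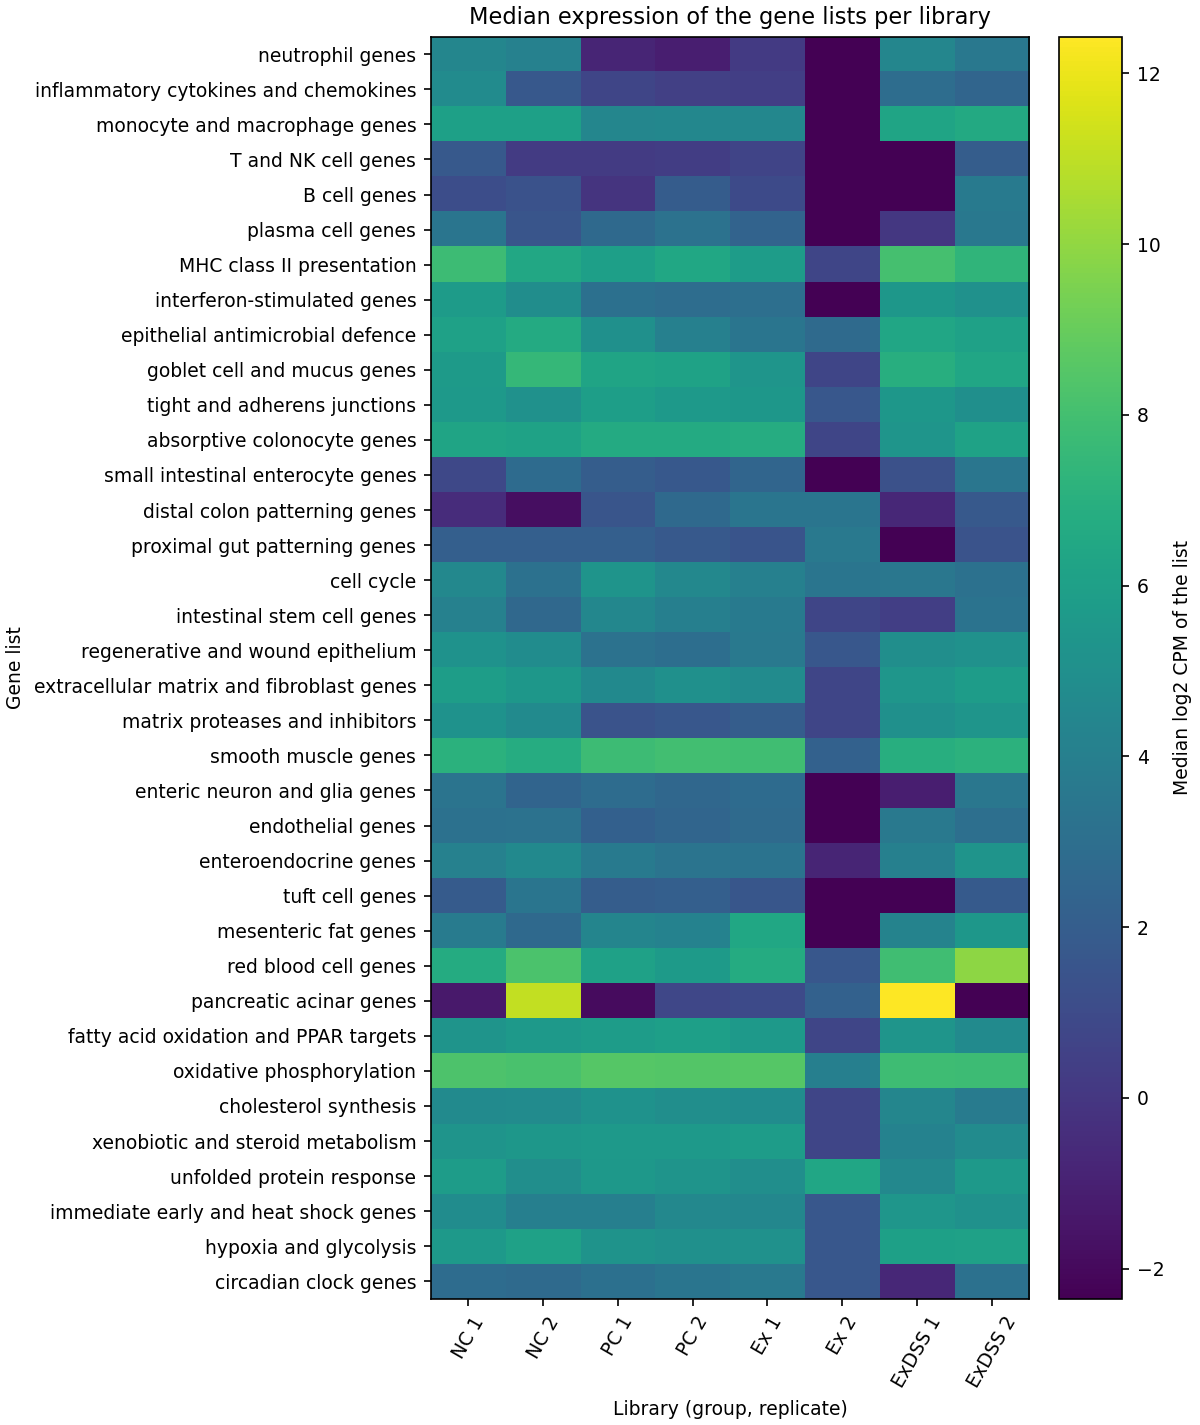
Median log2 CPM (colour scale) of the members of 36 gene lists (vertical axis) in each of the 8 libraries (horizontal axis). Neutrophil genes have medians of 4.43, 4.15, 4.42 and 3.59 in the libraries labelled NC and ExDSS and at most 0.15 in those labelled PC and Ex, and pancreatic acinar genes stand out in NC 2 and ExDSS 1.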

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

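Chosen only after the results were seen were the tests of pancreatic RNA or missing transcripts in NC 2, of few starting molecules, of counts taken by Rn45s and of the exosome treatment in Ex 2, and the edgeR fit without NC 2, Ex 2 and ExDSS 1. The interaction test, which asks whether the effect of DSS differed between mice with and without exosomes, called 42 genes with edgeR (2741 at an unadjusted p under 0.05; 1659 by DESeq2 and 327 by limma-voom). It called 0 genes without NC 1, NC 2 or ExDSS 1 (3061, 1772 and 2637 at an unadjusted p under 0.05), 0 without both libraries with pancreatic transcripts (3382), 0 with a term for libraries with missing transcripts (333) and 6 with total counts. At this threshold the calls thus depend on the scaling and on keeping each of these libraries. Leaving out a library leaves its group with 1, so lost power alone could end the calls. These counts do not show that the pattern rests on 1 library. The term was estimated from NC 1 and NC 2 alone, since both ExDSS libraries carry it, and cannot show what missing transcripts did. Each log2 interaction adds the log2 differences of ExDSS from Ex and of NC from PC. The log2 interactions were 21.50 for Slc6a19, 21.26 for Stfa2l1, 20.75 for S100a8, 19.82 for Mmp8, 19.50 for Wfdc12, 19.07 for S100a9, 18.10 for Chil3, 17.91 for Irg1, 16.68 for Cxcl10, 16.56 for Serpina3h, 15.95 for Saa3 and 15.66 for Serpina3f. They were 15.38 for Il1b, 14.10 for Serpina3n, 13.78 for Il11, 12.46 for Serpina3g, 12.02 for Lcn2, 12 for Cxcl5, 11.23 for Gbp5 and 10.95 for Cxcl9. Negative values were those of Bbc3 (-15.89), Aar2 (-14.62) and Kif20b (-11.85). By gene list, the median log2 interactions were 10.78 for neutrophil genes, 9.26 for cytokines and chemokines, 5.90 for interferon-stimulated genes, 5.85 for monocyte and macrophage genes, 4.53 for matrix proteases and inhibitors, 3.83 for antimicrobial defence genes and 21.05 for pancreatic acinar genes. These medians include fitted values of genes with no count in a group, which are not bounds. With such groups set at the floor they were 9.15, 4.23 and 5.24 for the first 3 lists and 20.66 for pancreatic genes. No list passed with an estimated correlation, a test that also missed a simulated 4-fold change of 1 list at the spread of these libraries.

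The median log2 CPM of neutrophil and interferon-stimulated genes was higher in NC 1 and NC 2 (4.43 and 4.15; 5.75 and 4.87) than in PC 1 and PC 2 (-0.84 and -1.09; 3.12 and 2.96), while that of cytokine genes was 4.76 in NC 1 and 1.70 in NC 2 against 0.72 and 0.46, and edgeR called 0 genes between PC and NC (363 at an unadjusted p under 0.05, 85 by DESeq2, 2 by limma-voom). Pancreatic RNA or missing transcripts in NC 2 were argued against as the cause for neutrophil genes, because NC 1, which had neither, lay 5.27 log2 units above the higher PC library in the median of the neutrophil genes. If the labels of NC and PC were exchanged, log2 ratios of NC 1 to PC should go with those of ExDSS 2 to Ex 1, and the correlation across 14567 genes, which are not independent replicates, was r = 0.487 (0.471 without 6 immune and protease lists), or -0.352 between PC against NC and ExDSS against Ex in the edgeR fit of these libraries. An exchange of the 2 groups' labels may therefore account for the pattern. The correlation alone cannot tell it from an exchange of the Ex and ExDSS labels, which would give the same sign. Inflammation of the NC mice from another source, or a response to DSS of opposite sign with and without exosomes, would also give a positive correlation. These stay open. The gut region is not given in the sources used here. Distal colon patterning genes had a median log2 CPM of -0.46 in NC 1 against 1.53 and 2.68 in PC 1 and PC 2. It was 1.76 in ExDSS 2 against 3.38 in Ex 1. Whether a difference in region added to the correlation was not tested. The groups were analysed as labelled throughout. Under an exchange, PC against NC would change sign and the interaction test would compare DSS with no DSS. ExDSS against PC would then set both treatments against neither, and Ex against NC would set exosomes against DSS. The pooled DSS effect would become the test of the interaction.

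Of 4895 genes picked as abundant in NC 1, PC 1, PC 2 and Ex 1, 2.19%, 10.9% and 1.98% were missing from NC 2, ExDSS 1 and ExDSS 2, while of 2980 genes picked as abundant in these 3 libraries 0.0671%, 0.738%, 0.638% and 0.336% were missing from NC 1, PC 1, PC 2 and Ex 1. Sequencing depth was argued against, since NC 1 thinned to each library's total outside the pancreatic genes lost 0 of the 4895 genes (mean of 20 draws), against 107, 534 and 97 missing from NC 2, ExDSS 1 and ExDSS 2. The share missing was higher among genes with a low GC content of the 3' end, with ratios between the lowest and highest of 3 equal groups of genes of 2.26, 2.21 and 3.14 in these libraries, which leaves a part for GC content open. Loss at random from few starting RNA molecules would make losses independent, and genes missing from both libraries of a pair were 3.05 times as many as independent losses give (127 against 41.7, 95% interval 2.56 to 3.52), which could be a random loss added to a shared one and leaves this explanation open. The interval comes from resampling genes, which are not independent replicates, and does not cover the spread between libraries.

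Abundant intestinal transcripts were missing from Ex 2, in which 310 of the 500 most abundant genes of Ex 1 were under 10 percent of their level there. Lower depth was argued against, since Ex 1 thinned to 541286 counts had 0 such genes (mean of 20 draws). Counts taken by Rn45s were also argued against, because the median log2 ratio of Ex 2 to Ex 1 over 26 absorptive colonocyte genes was -6.23 with Rn45s left out of the totals. The exosome treatment was argued against as the cause, since 3 of the 500 genes most abundant in PC were under 10 percent of that level in Ex 1 and 296 in Ex 2. Another source of the RNA in Ex 2 was not tested.

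For the pooled effects edgeR called 0 genes each (80 for DSS and 255 for exosomes at an unadjusted p under 0.05; 24 and 35 by DESeq2, 0 and 0 by limma-voom). With 0 called by the real split, every split of the 8 libraries into 4 and 4 calls as many (35 of 35 for DSS and 35 of 35 for exosomes), so this count is fixed and chance is not excluded. The highest other split called 47 genes in the DSS model and 56 in the exosome model. Both came from setting NC and ExDSS against PC and Ex. This is the comparison that the interaction tests, so these counts restate that result and add no support to it. As labelled, this split follows neither treatment alone. If the labels of NC and PC were exchanged, it would follow DSS.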

How the results depend on the processing

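Chosen after the data were seen were the fits without NC 2 and ExDSS 1, without NC 2, Ex 2 and ExDSS 1, with a term for libraries with missing transcripts, without Rn45s, and the correlation without missing genes. Between groups, the term was estimated from NC 1 and NC 2 alone, so its counts cannot show what missing transcripts did. Counts below are genes called for PC against NC, ExDSS against PC, Ex against NC, ExDSS against Ex and the interaction, against 0, 0, 0, 0 and 42 as reported. Without a filter on low counts they were 45, 132, 55, 223 and 350. With DESeq2 they were 85, 1515, 338, 2089 and 1659, with 24 for DSS and 35 for exosomes over all libraries, against 0 and 0 with edgeR (80 and 255 at an unadjusted p under 0.05). With limma-voom they were 2, 1160, 0, 505 and 327. RLE and upper-quartile factors, TMM without the 50 most abundant genes, the fit without the robust option and fits of only the groups compared called 0 genes between any pair of groups. With the replicate number as a replicate block they were 0, 41, 0, 28 and 161; deviations of same-numbered libraries correlated between -0.207 and 0.082, so the numbers were not taken to pair samples. The interaction count was 67 with RLE factors (46 positive, 21 negative, against 38 and 4), 40 with upper-quartile factors (31 and 9), 6 with total counts, 25 with at least 10 counts in 4 libraries, 39 with TMM without the 50 most abundant genes, 41 without the robust option, 42 without Rn45s and 115 at an adjusted p under 0.1. Without the 3 libraries NC 2, Ex 2 and ExDSS 1 the counts were 3677, 10496, 3361, 9541 and 9416, with 1 residual degree of freedom, from the PC pair. The interaction count was 0 without the 2 libraries with pancreatic transcripts, 0 with a term for the 3 libraries with missing transcripts and 0 with that term and Ex 2 left out (3382, 333 and 909 at an unadjusted p under 0.05). Leaving out 1 library at a time gave 0 to 3 genes, 0 to 6, 0 to 1619, 0 to 1914 and 0 to 1700, each highest count without Ex 1 except 6 for ExDSS against PC, without Ex 2, and 3 for PC against NC, without Ex 1 or without Ex 2. The lone library of a group was then assumed to vary like the others. Of 104 list calls over 7 contrasts, 0 held with an estimated correlation and fry called 3; leaving out 1 library gave 77 to 112. The correlation of the DSS responses ran from -0.498 without Ex 2 to -0.279 without Ex 1, and was -0.334 without NC 2 and ExDSS 1, -0.352 without NC 2, Ex 2 and ExDSS 1 and -0.470 without 623 missing genes. Apart from fewer genes or libraries, the cause was not tested.

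Of 4286 alternative fits of 182 named pairs of gene and contrast, 2848 planned and 699 added fits kept direction and side of the threshold, 330 and 110 gained a call, 185 and 69 lost one (all in the interaction), and 17 and 27 moved. The 1 reversal was Reg1 in ExDSS against PC, -5.971 without NC 2, Ex 2 and ExDSS 1 against 12.20; that fit sets ExDSS 2 alone, at 0, against PC at under 1 CPM, so its value depends on how a 0 is treated and is no bound. Fits of the return towards saline levels, and of the size of the DSS response over called genes, were not run, since 0 genes were called by edgeR in PC against NC (363 at an unadjusted p under 0.05, 85 by DESeq2, 2 by limma-voom). At the depth of Ex 2, a count of 0 allows 4.47 CPM.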

Other observations

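The genes below were chosen after their values were seen, and values are normalised CPM of single libraries. Hoxb13, a patterning gene of the distal colon, had 83.1 and 152 CPM in PC 1 and PC 2 and 183 CPM in Ex 1, against at most 18.1 CPM in the other 5 libraries. Fat cell genes were highest in Ex 1 for Adipoq (170 CPM) and Car3 (343 CPM), and in ExDSS 2 for Cfd (1615 CPM). The haemoglobin genes Hba-a1 and Hbb-bs were highest in ExDSS 2, at 2416 and 1918 CPM. Reg3b, an antibacterial lectin gene, had 6657 and 5490 CPM in NC 1 and NC 2, 8821 CPM in ExDSS 1 and 87.0 CPM in ExDSS 2, and 714 CPM in PC 1 against 2.75 CPM in PC 2. Reg3g followed the same order in these libraries, from 3109 CPM in NC 1 to 1.57 CPM in PC 2, except that ExDSS 1 (1703 CPM) lay below both NC libraries.

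In ExDSS 2 the goblet cell genes Clca1 and Fcgbp had 22780 and 3130 CPM, against 4297 and 906 CPM in ExDSS 1, while Muc2 had 1494 and 647 CPM. Insl5, a hormone gene of the colon, had 1316 CPM in ExDSS 2 and 118 CPM in ExDSS 1. Aqp8 and Car1, genes of absorptive colon cells, had 1034 and 4396 CPM in Ex 1 and 1.49 and 13.4 CPM in Ex 2. Ex 2 in turn had 11240 CPM of Pabpc1, which binds poly(A) tails, 7218 CPM of Stc1 and 5724 CPM of Hsp90b1, a chaperone gene, against 439, 2.56 and 490 CPM in Ex 1. In Ex 2, 312 genes were over 10 times their highest level in the other libraries (plus 1 CPM) and held 20.9% of its counts outside Rn45s.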
